A study of Mus musculus with 57 samples.

How the data were processed

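Poly(A) RNA of mouse prefrontal cortex was sequenced from strand-specific libraries made with the TruSeq Stranded mRNA kit, per the labels' protocols. The deposited table holds 1 row per gene and 1 column per library. Its values are a signal of gene counts divided by 1 size factor per library, as deposited by the authors. The tools named are Salmon 0.11.2, R 3.6.0 and DESeq2 1.19.11 with the genome build GRCm38, per the submitters' processing notes, which give no role or order. The rule by which the 18088 listed genes were chosen is not given in the sources used here, and 3 of them are listed at 0 in every library used. Because the size factors scale each library as a whole, a change in total RNA per cell cannot be seen, and gene-level values join all transcripts of a gene.

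The table has 59 columns. Columns were matched to samples by the end of the library name in the labels, and 3 columns that match no sample were not used. The labels list 57 samples, and 1 of them, a WT lithium female, has no matching column and was not analysed here, which left 56 libraries. Every value was a whole multiple of the smallest value above 0 in its column (100% of values within 1e-06 of a whole number), so whole reads could be recovered. They numbered 22984556 to 35969254 per library, which sets the counting error. No pair of libraries of 1 group agreed within sampling noise: over 105 pairs the smallest chi-square per degree of freedom was 4.94. Gene symbols came from a table of identifiers, which matched 18077 of the 18088 genes, and coordinates and the length and GC content of each gene's longest transcript from the GENCODE annotation of GRCm38.

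Values were analysed as log2(value + 1), so fold changes of low genes are understated. Genes with a value of at least 10 in at least 3 libraries were tested (18026 genes). All 12 groups entered 1 limma-trend fit (limma 3.58.1, R 4.3.3), with 44 residual degrees of freedom, and each comparison was a contrast of group means, two-sided, called at a Benjamini-Hochberg adjusted p below 0.05 over the genes of that contrast. There were 7 comparisons with the sexes averaged, 10 within a sex, 5 differences between the sexes (males minus females) and 2 interactions of drug and genotype. edgeR 4.0.16 (quasi-likelihood, TMM) was run on the recovered reads as an alternative. Across 33 gene lists fixed before the data were examined, camera was run with a preset correlation of 0.01 and with an estimated one. With the estimated correlation no list was called in any comparison. The fry test, which asks whether a list moves one way on balance and does not compare it with other genes, was run beside it. A list's adjusted p covers the 33 lists within a comparison. Correlations of effects across genes were set against 100 simulated data sets in which residuals were shuffled over libraries within each sex.

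The genes named were chosen by a rule fixed before the data were examined: Shank3; for each comparison with the sexes averaged the 10 called genes with the largest rise and the 10 with the largest fall, or, where fewer than 5 were called, those with the smallest p, as values; from each list up to 4 called members with the smallest p, or up to 2 as values; within a sex, and for differences, up to 5 called genes; and the sex genes and drug targets. Predicted genes and pseudogenes were not named, and the text names part of those the rule gives; some are not reported here. Several whose calls ended under other settings were left out of the text. Where a list member outside the rule is given, it was chosen after its values were seen.

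The alternatives planned before the data were examined were limma without the trend, TMM factors on the deposited values, no filter on low values, a pseudocount of 5, the compared groups only, the replicate number as a block, the score of striatal markers as a covariate, array weights, and leaving out each library in turn. Those chosen after exploring the data, and with their effect on the counts known, were edgeR on the recovered reads, the olfactory level as a covariate, a correction within each library of the trend with GC content and length (splines with 4 degrees of freedom each), both together, and leaving out either the 2 libraries more than 5 median absolute deviations from the median in choroid plexus or mitochondrially encoded genes, or the 14 libraries of highest olfactory level. The fits were tested on simulated counts over 18026 genes, 100 of them changed by 0.5 and 100 by 1 on the log2 scale. For lithium against vehicle in HT with the sexes averaged, limma recovered 60% and 88%, with 8 false among 156 calls. For fluoxetine against vehicle in WT females it recovered 50% and 81%, with 5 false among 136 calls. For HT against WT in vehicle males it recovered 37% and 77%, with 12 false among 126 calls. These rates hold for the simulation only: with labels exchanged, WT fluoxetine and vehicle females gave up to 4230 calls.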

Results

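RNA of the prefrontal cortex, the front part of the cerebral cortex, was sequenced from C57BL/6J mice. The mice were wild type (WT) or heterozygous (HT) for the Shank3 delta C allele. Shank3 encodes a scaffold protein of the postsynaptic density of excitatory synapses. The mice had received vehicle, fluoxetine (an inhibitor of serotonin reuptake) or lithium (a mood stabiliser that inhibits GSK3 and inositol monophosphatase) through their mothers' milk. Treatment lasted 3 weeks, from postnatal day 3 to 24, and the tissue was taken on postnatal day 25. Genotype, drug and sex made 12 groups. Of these, 9 held 5 libraries each, WT lithium females and HT lithium males held 4 each and HT vehicle males held 3, for 56 libraries. The reads recovered over the listed genes numbered from 22984556 to 35969254 per library. Litters are not named in the labels, so the p-values treat mice as independent although pups of 1 dam shared its milk.

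Xist, the RNA of the inactive X chromosome, lay between 11388 and 39198 normalised counts in the female libraries and between 0 and 10.1 in the male ones. The Y-linked Ddx3y lay between 1178 and 1953 in males and did not exceed 3.29 in females. 0 libraries went against their labelled sex. Markers of the olfactory bulb, a neighbouring region, varied between libraries of the same group. The olfactory level is the mean over Eomes, Doc2g, Cdhr1, Th and Trh of each gene's value relative to its mean over libraries. It was 2.28 ± 2.09 (SD, n = 5) in WT fluoxetine females, where single libraries ranged from 0.077 to 4.41. In HT lithium females it was 1.39 ± 1.24 (SD, n = 5), in HT vehicle females 0.86 ± 1.03 (SD, n = 5), in WT vehicle males 1.14 ± 0.77 (SD, n = 5) and in HT lithium males 0.14 ± 0.07 (SD, n = 4). Libraries also differed in the slope of their log2 values with the GC content of the transcript. Per 10 percentage points it was -0.077 ± 0.073 (SD, n = 5) in WT vehicle females and 0.092 ± 0.069 (SD, n = 5) in WT fluoxetine females.

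**Figure D1:**
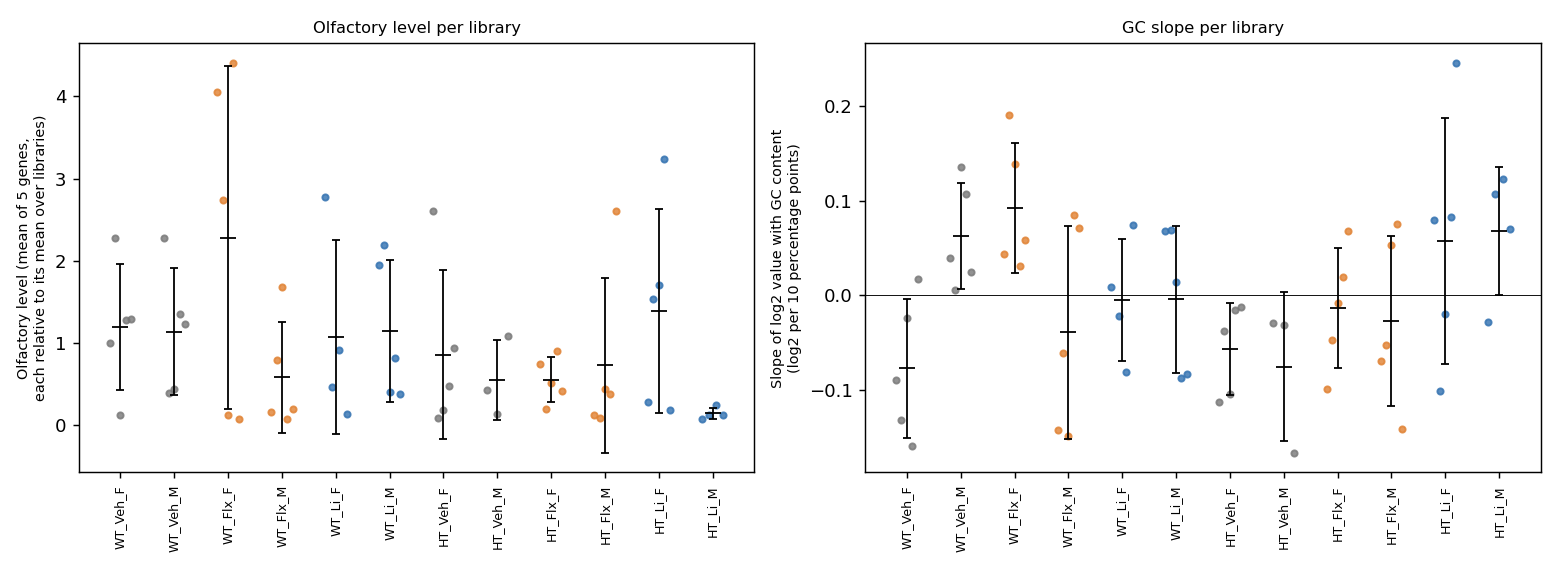
The left panel plots the olfactory level and the right panel the slope of log2 values with GC content for each library (points; grey vehicle, orange fluoxetine, blue lithium). The horizontal axis gives genotype, drug and sex, and bars the group means and SD. WT fluoxetine females had the highest mean of both, 2.28 and 0.092.

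Shank3 itself (ENSMUSG00000022623, chromosome 15, 89499623 to 89560261, GRCm38) had a normalised count of 7524 ± 1032 (SD, n = 5) in HT vehicle females and 6910 ± 713 (SD, n = 5) in WT vehicle females. In vehicle males it was 7921 ± 368 (SD, n = 3) in HT and 8002 ± 420.3 (SD, n = 5) in WT. The log2 fold change of HT over WT was 0.05 ± 0.09, adjusted p = 0.915. The labels do not say which part of the gene the allele changes, so this gene-level value does not check the genotype labels.

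The comparison of HT with WT under vehicle asks what the allele alone changed. With the sexes averaged, 0 of 18026 tested genes passed the limma-trend test, and edgeR on the recovered reads called 0. In the limma fit 1119 genes had an unadjusted p under 0.05, against 901.3 by chance. Fold changes here and below are log2 values ± SE. The smallest p on the higher side belonged to Txlng (0.26 ± 0.07), Fam118b (0.26 ± 0.07) and Pkp2 (0.57 ± 0.15). On the lower side they were Acads (-0.37 ± 0.08), Lmo2 (-0.29 ± 0.07) and Pdgfrb (-0.29 ± 0.07), and the smallest adjusted p was 0.521. The 22 markers of myelinating oligodendrocytes had a median log2 change of -0.32, with 0 called. Camera on the myelin markers gave adjusted p = 5.64e-08, adjusted p = 0.465 with an estimated correlation, and 0 members adjusted over the list alone. The 79 cytosolic ribosomal protein genes had a median of -0.09, with 0 called. Camera on the ribosomal protein genes, with a median of 0.02 in females and -0.22 in males, gave adjusted p = 1.12e-13, adjusted p = 0.465 with an estimated correlation, and 0 members adjusted over the list alone.

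Immediate early genes, which respond to neuronal activity, had a median of -0.36 in HT against WT under vehicle, with 0 of 24 called. Camera on the immediate early genes, with a median of 0.07 in females and -0.56 in males, gave adjusted p = 2.17e-05, adjusted p = 0.465 with an estimated correlation, and 0 members adjusted over the list alone. Fosb and Btg2 had -0.68 ± 0.26, adjusted p = 0.719 and -0.49 ± 0.20, adjusted p = 0.742. The 19 glucocorticoid-responsive genes had a median of 0.13, with 0 called. Camera on the glucocorticoid-responsive genes, with a median of -0.05 in females and 0.24 in males, gave adjusted p = 0.00206 (7.81e-07 to 0.0646 over other settings, highest with array weights), adjusted p = 0.465 with an estimated correlation, and 6 higher and 0 lower members adjusted over the list alone. Markers of the choroid plexus, which produces cerebrospinal fluid, had a median of 0.43 with 0 of 11 called, and 1 library, HT vehicle female replicate 1, lay 5.30 log2 units above the median library in them. Camera on the choroid plexus markers gave adjusted p = 0.00122 (4.85e-06 to 0.661 over other settings, highest without the 2 libraries apart), adjusted p = 0.466 with an estimated correlation, and 0 members adjusted over the list alone. In this comparison camera also called GABA receptors (0.07, females -0.03, males 0.19), astrocyte markers (-0.07), oligodendrocyte progenitor markers (-0.08), endothelial and pericyte markers (-0.06, females 0.02, males -0.10), olfactory and thalamic markers (-0.30), Wnt target genes (-0.12) and endoplasmic reticulum stress genes (0.05) (medians), at adjusted p from 0.00713 to 0.0431, and adjusted p of at least 0.465 with an estimated correlation. GABA receptors, oligodendrocyte progenitor markers, olfactory and thalamic markers and endoplasmic reticulum stress genes lost the call under other settings. The number of called genes was 1 with compared groups only, 2 with array weights and 4 without the 14 most olfactory libraries. It was 1 without HT vehicle male replicate 2.

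Within males, 47 genes differed between HT and WT under vehicle, 28 higher and 19 lower in HT. Among those higher were Mc4r, the melanocortin 4 receptor (1.40 ± 0.30, adjusted p = 0.0227), the kinase gene Map3k6 (1.18 ± 0.23, adjusted p = 0.0153) and Tlr7, a receptor of innate immunity (1.06 ± 0.19, adjusted p = 0.00882). Among those lower were Tnfsf10 (-1.13 ± 0.26, adjusted p = 0.0369), Sox9, a transcription factor of astrocytes (-0.83 ± 0.16, adjusted p = 0.00882), and Cdc42ep1 (-0.87 ± 0.18, adjusted p = 0.0179). In females 0 genes were called by limma and 1 by edgeR, with 385 genes at an unadjusted p under 0.05. The difference between the sexes called 0 genes with limma and 0 with edgeR, with 1574 at an unadjusted p under 0.05, so a genotype effect limited to males was not shown. The male count was 16 with compared groups only, 21 with the replicate block, 960 with array weights, 118 with the olfactory covariate, 18 with GC and length correction and 220 without the 14 most olfactory libraries. It was 30, 10 and 1 without HT vehicle male replicates 1, 2 and 3, and 86, 18, 1 and 16 without WT vehicle male replicates 1, 3, 4 and 5. Among these genes, calls ended with compared groups only for Mc4r, Map3k6, Tlr7 and Tnfsf10, with the replicate block for Mc4r, with GC and length correction for Cdc42ep1. Mc4r (4), Cdc42ep1 (4), Sox9 (3), Map3k6 (4), Tnfsf10 (5) and Tlr7 (2) lost calls without any 1 of that many libraries. The female count was 1 with edgeR. The count for the difference was 6 with compared groups only, 3 with the striatal covariate, 151 with array weights, 3 with GC and length correction, 5 with GC, length and olfactory correction, 4 without the 2 libraries apart and 27 without the 14 most olfactory libraries. It was 3 without HT vehicle female replicate 1, 4 without HT vehicle male replicate 2, 5 without WT vehicle female replicate 3, and 18 without WT vehicle male replicate 1.

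**Figure D2:**
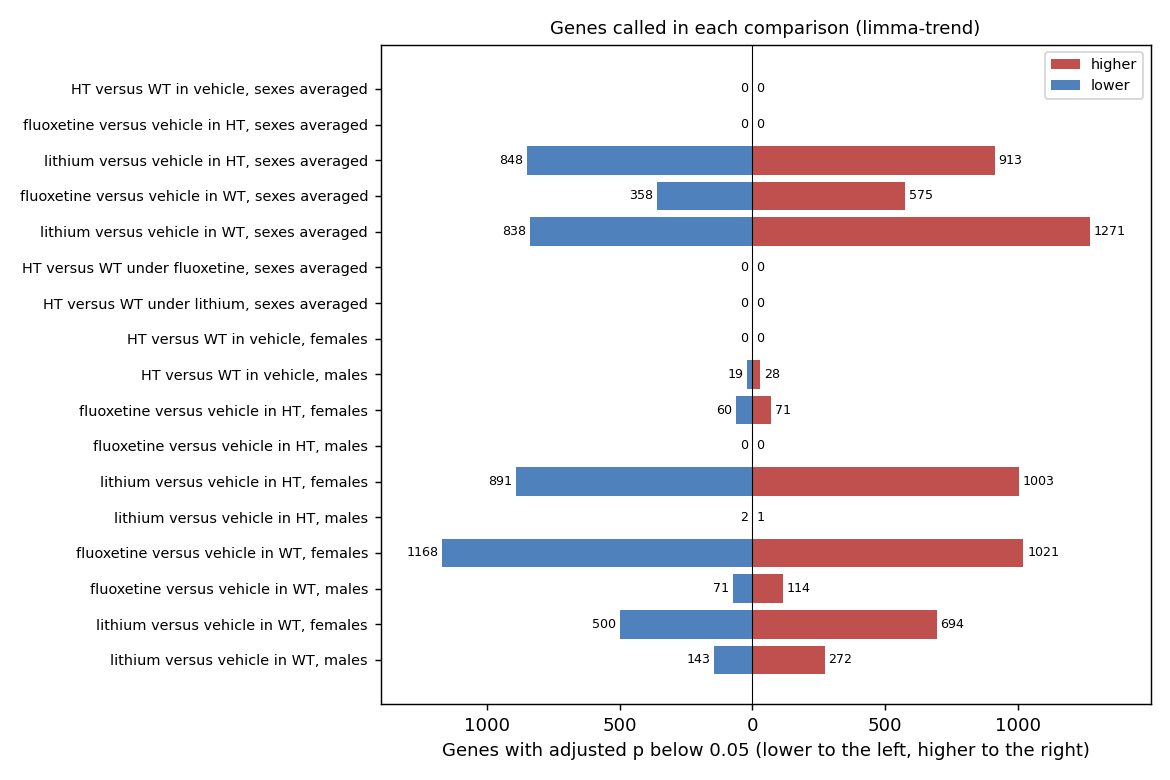
Bars give the genes with an adjusted p below 0.05, higher to the right and lower to the left, for the comparisons on the vertical axis. With the sexes averaged, lithium called 1271 genes higher and 838 lower in WT, and 913 and 848 in HT.

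Lithium against vehicle in WT mice changed 2109 genes, 1271 higher and 838 lower. Of 19 glucocorticoid-responsive genes, 9 rose and 0 fell. Camera on the glucocorticoid-responsive genes gave adjusted p = 5.93e-07, adjusted p = 0.177 with an estimated correlation, and 10 higher and 1 lower members adjusted over the list alone. The fry test of a common direction gave these genes adjusted p = 1.88e-04. Zbtb16, a zinc finger transcription factor, rose by 0.86 ± 0.09, adjusted p = 2.93e-09. Its normalised count was 795 ± 190.5 (SD, n = 5) under vehicle and 1570 ± 133 (SD, n = 5) under lithium in males, and 806 ± 128 (SD, n = 5) and 1326 ± 209 (SD, n = 4) in females. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 0.78 ± 0.13, adjusted p = 6.56e-05, and Hif3a by 0.96 ± 0.17, adjusted p = 7.75e-05. Lcn2 and Plin4 of the same list were among the 10 largest rises of called genes, predicted genes aside (1.67 ± 0.40, adjusted p = 0.00407, and 1.17 ± 0.29, adjusted p = 0.00542).

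Of 18 genes of the endoplasmic reticulum stress response, 10 rose and 0 fell under lithium in WT. Camera on the endoplasmic reticulum stress genes gave adjusted p = 1.13e-08, adjusted p = 0.177 with an estimated correlation, and 12 higher and 0 lower members adjusted over the list alone. They included Dnajc3 (0.33 ± 0.06, adjusted p = 1.58e-04) and Pdia4, a protein disulfide isomerase (0.42 ± 0.08, adjusted p = 3.56e-04). Herpud1 and Hyou1 rose by 0.27 ± 0.05, adjusted p = 3.85e-04 and 0.30 ± 0.06, adjusted p = 4.48e-04. Slc5a3, the sodium-coupled myo-inositol transporter, rose by 0.49 ± 0.09, adjusted p = 1.36e-04, and Isyna1, the inositol phosphate synthase, by 0.27 ± 0.08, adjusted p = 0.0229. The known lithium targets Gsk3a, Gsk3b and Impa1 had -0.09 ± 0.06, adjusted p = 0.399, 0.11 ± 0.05, adjusted p = 0.187 and 0.10 ± 0.05, adjusted p = 0.144. Among 18 circadian clock genes 4 rose and 1 fell, with Per2 at 0.58 ± 0.09, adjusted p = 1.77e-05 and Per3 at 0.25 ± 0.07, adjusted p = 0.0147. Camera on the clock genes gave adjusted p = 0.0199 (0.00687 to 0.123 over other settings, highest with GC, length and olfactory correction), adjusted p = 0.68 with an estimated correlation, and 7 higher and 1 lower members adjusted over the list alone. Postsynaptic density scaffolds rose in 9 of 30 genes, such as Synpo (0.34 ± 0.08, adjusted p = 0.00324) and Nlgn3 (0.20 ± 0.06, adjusted p = 0.0154). Camera on the postsynaptic density scaffolds gave adjusted p = 0.00635 (2.47e-04 to 0.993 over other settings, highest with GC, length and olfactory correction), adjusted p = 0.906 with an estimated correlation, and 11 higher and 0 lower members adjusted over the list alone.

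Cytosolic ribosomal protein genes fell in 20 of 79 cases under lithium in WT, with Rpl23 at -0.27 ± 0.06, adjusted p = 0.00143 and Rps3a1 at -0.20 ± 0.05, adjusted p = 0.00354. Camera on the ribosomal protein genes gave adjusted p = 7.07e-10 (1.38e-13 to 0.115 over other settings, highest with GC, length and olfactory correction), adjusted p = 0.68 with an estimated correlation, and 0 higher and 25 lower members adjusted over the list alone. Microglial markers fell in 4 of 20, among them P2ry13, a purine receptor (-0.53 ± 0.10, adjusted p = 1.53e-04), and Cx3cr1, the fractalkine receptor (-0.26 ± 0.08, adjusted p = 0.0229). Camera on the microglial markers gave adjusted p = 2.84e-04, adjusted p = 0.68 with an estimated correlation, and 0 higher and 7 lower members adjusted over the list alone. Cholesterol biosynthesis genes fell in 5 of 24, with Insig1 at -0.32 ± 0.06, adjusted p = 4.93e-04. Camera on the cholesterol genes gave adjusted p = 2.21e-04, adjusted p = 0.714 with an estimated correlation, and 0 higher and 7 lower members adjusted over the list alone. Of 53 autism risk genes, 14 rose and 1 fell. Camera on the autism risk genes gave adjusted p = 2.64e-05 (2.39e-06 to 0.848 over other settings, highest with GC and length correction, direction turned with GC and length correction and with GC, length and olfactory correction), adjusted p = 0.201 with an estimated correlation, and 18 higher and 1 lower members adjusted over the list alone. Med13l, Tsc2 and Kmt2a rose by 0.21 ± 0.04, 0.23 ± 0.04 and 0.33 ± 0.06, while Ctnnb1, which encodes beta-catenin, had -0.27 ± 0.04, adjusted p = 2.77e-05.

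Noxred1 also rose under lithium in WT (1.17 ± 0.18, adjusted p = 1.08e-05). Prnd and Aplnr, the apelin receptor, fell (-1.64 ± 0.45, adjusted p = 0.011, and -1.02 ± 0.27, adjusted p = 0.00774). Under lithium in WT camera also called myelin markers (-0.19), inositol phosphate and GSK3 genes (0.05) and oxidative phosphorylation genes (-0.06) (medians), at adjusted p from 0.00153 to 0.0457, and adjusted p of at least 0.177 with an estimated correlation. All of these lost the call under other settings, and the direction of oxidative phosphorylation genes turned. The count was 3349 with array weights and 3486 with the olfactory covariate. For lithium in WT, calls ended with compared groups only for Prnd, with GC and length correction for Nlgn3, Rpl23, Rps3a1, Med13l, Kmt2a and Per3, without the 14 most olfactory libraries for Isyna1. Cx3cr1 (3), Prnd (1) and Isyna1 (1) lost calls without any 1 of that many libraries.

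In HT mice lithium against vehicle changed 1761 genes, 913 higher and 848 lower. Of the 18 endoplasmic reticulum stress genes, 12 rose and 1 fell. Camera on the endoplasmic reticulum stress genes gave adjusted p = 2.08e-08, adjusted p = 0.524 with an estimated correlation, and 13 higher and 1 lower members adjusted over the list alone. Sdf2l1 rose by 0.68 ± 0.12, adjusted p = 2.27e-04. Its normalised count in males was 219.6 ± 23.6 (SD, n = 3) under vehicle and 382 ± 45.7 (SD, n = 4) under lithium. Calr and Hyou1, chaperones of the endoplasmic reticulum, rose by 0.28 ± 0.06, adjusted p = 8.96e-04 and 0.28 ± 0.06, adjusted p = 0.00238. Hspa5, the chaperone BiP, rose by 0.37 ± 0.09, adjusted p = 0.00511, and Ddit3, the transcription factor CHOP, by 0.36 ± 0.08, adjusted p = 0.00363.

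Postsynaptic density scaffolds rose in 8 of 30 genes under lithium in HT. Camera on the postsynaptic density scaffolds gave adjusted p = 4.22e-07, adjusted p = 0.524 with an estimated correlation, and 10 higher and 1 lower members adjusted over the list alone. They included Shank1 (0.52 ± 0.09, adjusted p = 1.51e-04), Dlgap4 (0.24 ± 0.05, adjusted p = 4.80e-04) and Nlgn2 (0.33 ± 0.07, adjusted p = 0.00148). Shank3, which was not in the list, rose by 0.34 ± 0.09, adjusted p = 0.0127. Its normalised count was 9279 ± 1147 (SD, n = 5) in HT lithium females and 10333 ± 584 (SD, n = 4) in HT lithium males. In WT the lithium effect on Shank3 was 0.06 ± 0.09, adjusted p = 0.751, and the test of the difference between genotypes did not call it. The Shank3 rise in HT was 0.12, adjusted p = 0.523 with GC and length correction and 0.28, adjusted p = 0.0562 without the 2 libraries apart. The GC slope was 0.057 ± 0.130 (SD, n = 5) in HT lithium females and -0.056 ± 0.049 (SD, n = 5) in HT vehicle females. Replicate 5 of the HT lithium females, 1 of the 2 libraries apart, had a slope of 0.246 and lay at -1.64 log2 units in mitochondrially encoded genes. In males it was 0.068 ± 0.068 (SD, n = 4) and -0.076 ± 0.079 (SD, n = 3). Astrocyte markers rose in 4 of 20, with Aldoc at 0.26 ± 0.08, adjusted p = 0.024. Camera on the astrocyte markers, with a median of 0.24 in females and -0.02 in males, gave adjusted p = 0.00117 (3.31e-05 to 0.0742 over other settings, highest without the 14 most olfactory libraries), adjusted p = 0.524 with an estimated correlation, and 5 higher and 0 lower members adjusted over the list alone. The brain proteoglycans Ncan and Bcan rose by 0.36 ± 0.06, adjusted p = 1.64e-04 and 0.31 ± 0.07, adjusted p = 0.00386. Tspan2 (-0.58 ± 0.15, adjusted p = 0.0112) was the 1 myelin marker of 22 that fell. Camera on the myelin markers gave adjusted p = 0.00117 (3.11e-05 to 0.824 over other settings, highest without the 14 most olfactory libraries, where their direction turned), adjusted p = 0.692 with an estimated correlation, and 0 higher and 1 lower members adjusted over the list alone.

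Of 19 glucocorticoid-responsive genes 3 rose and 1 fell under lithium in HT, also when adjusted over the list alone. Zbtb16 rose by 0.48 ± 0.09, adjusted p = 4.88e-04. Its HT counts were 697 to 870 in vehicle females, 1176 to 1226 in vehicle males and 1178 to 1631 under lithium. Camera (medians 0.30 in females, -0.07 in males) gave adjusted p = 0.146 and adjusted p = 0.72 with an estimated correlation. Per2 rose by 0.42 ± 0.10, adjusted p = 0.00307 and Ctnnb1 had -0.25 ± 0.05, adjusted p = 2.92e-04. Large rises outside the lists were those of Noxred1 (0.86 ± 0.19, adjusted p = 0.00224) and Lars2, the mitochondrial leucyl-tRNA synthetase (0.81 ± 0.19, adjusted p = 0.00377). Mlf1 (-0.92 ± 0.23, adjusted p = 0.00787) and Tacr3, the neurokinin 3 receptor (-0.76 ± 0.23, adjusted p = 0.0285), fell. Gsk3a, Gsk3b and Impa1 had -0.02 ± 0.07, adjusted p = 0.919, 0.06 ± 0.06, adjusted p = 0.605 and -0.14 ± 0.05, adjusted p = 0.0654. Camera also called GABA receptors (median -0.11), endothelial and pericyte markers (0.11), choroid plexus markers (-0.59) and immediate early genes (0.24). Their adjusted p was 0.0138 to 0.027, and at least 0.668 with an estimated correlation. All lost the call under other settings. The count of called genes was 3452 with array weights, 3168 with the olfactory covariate, 394 with GC and length correction and 3042 without the 14 most olfactory libraries. It was 995 without HT vehicle male replicate 3. For lithium in HT, calls ended with compared groups only for Aldoc, with GC and length correction for Shank3, Mlf1, Tacr3, Dlgap4, Nlgn2, Aldoc, Tspan2, Hyou1, Per2 and Bcan, without the 2 libraries apart for Shank3 and Tacr3, without the 14 most olfactory libraries for Mlf1, Aldoc and Tspan2. Tacr3 (4) and Aldoc (1) lost calls without any 1 of that many libraries.

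The lithium effects in HT and WT share no library. Of the called genes, 442 were higher in both genotypes, where independent lists would give 64.4. In both, 247 were lower, where independent lists would give 39.4, and 0 were called in opposite directions. Of the genes called in HT, 94.2% had the same sign in WT. Across all 18026 genes, which are not independent replicates, the log2 fold changes had Pearson's r = 0.34 (simulated range -0.47 to 0.49, covariance 0.0189, simulated 0.00043). Its permutation p was 0.0594, adjusted p = 0.327 over 6 correlations, and p was under 0.05 in 18 of 36 fits without 1 library. The lithium by genotype interaction called 3 genes. Nkd1, an inhibitor of Wnt signalling, fell in WT (-0.42 ± 0.08, adjusted p = 1.36e-04) and its change in HT was higher by 0.61 ± 0.11, adjusted p = 0.0211. Vwa1 and Nhsl2 had interactions of 0.64 ± 0.12, adjusted p = 0.0248 and -0.38 ± 0.07, adjusted p = 0.0248. The interaction count was 33 with array weights, 10 with the olfactory covariate, 1 with GC and length correction, 5 with GC, length and olfactory correction, 0 without the 2 libraries apart and 902 without the 14 most olfactory libraries. It was 1 without HT lithium female replicate 2, 0 without HT lithium male replicate 4, 1 without HT vehicle female replicate 5, 5 and 0 without HT vehicle male replicates 1 and 3, 0 without WT lithium female replicate 2, 0 and 1 without WT lithium male replicates 4 and 5, 1 and 1 without WT vehicle female replicates 3 and 5, and 0 without WT vehicle male replicate 4. Interaction calls ended with compared groups only for Nhsl2, with GC and length correction for Vwa1 and Nhsl2, without the 2 libraries apart for Nkd1, Vwa1 and Nhsl2. Vwa1 (10), Nhsl2 (12) and Nkd1 (5) lost calls without any 1 of that many libraries.

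**Figure D3:**
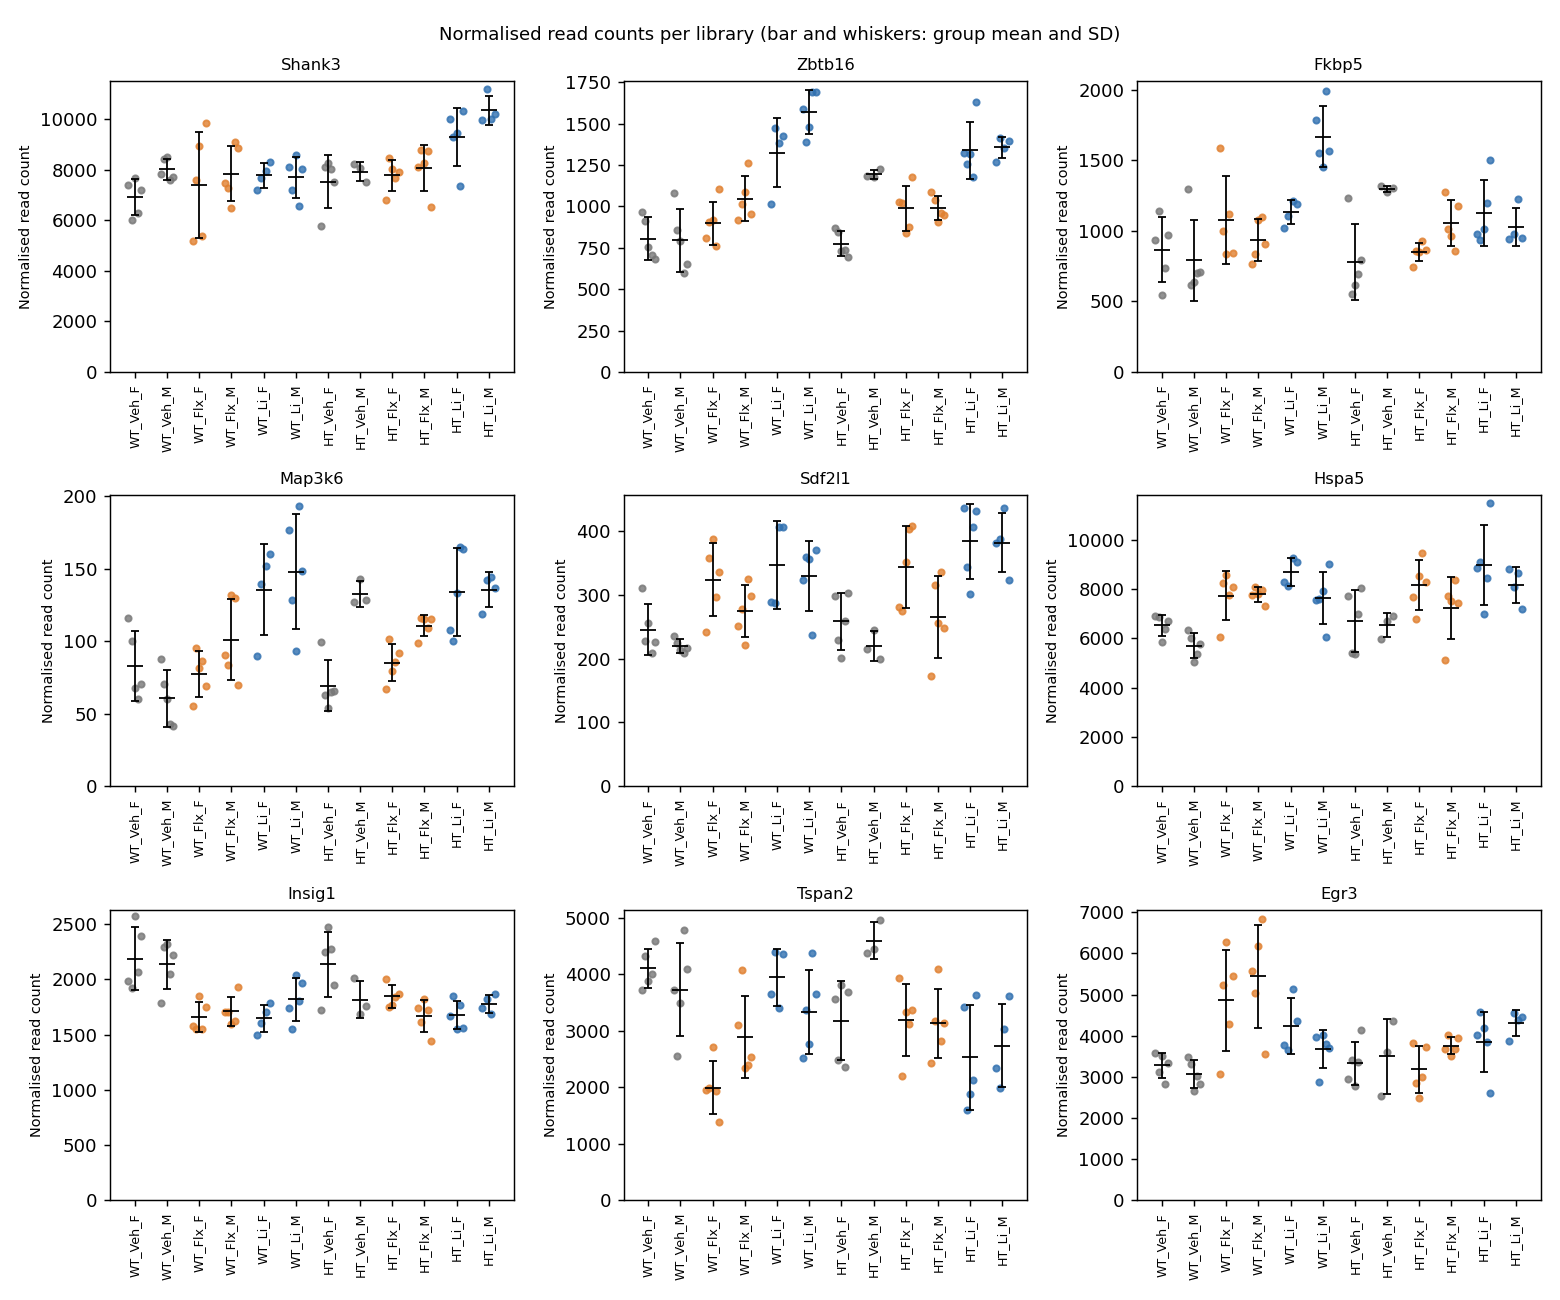
Each panel plots the normalised read count of 1 gene on a linear axis from 0, per library (points; grey vehicle, orange fluoxetine, blue lithium), with the group mean and SD, by genotype, drug and sex. Zbtb16 had higher means in the 4 lithium groups than in the others, 1570 ± 133 (SD, n = 5) in WT males, and Insig1 was 2188 ± 283 (SD, n = 5) in WT vehicle females and 1657 ± 137 (SD, n = 5) under fluoxetine.

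Fluoxetine against vehicle in WT mice changed 933 genes, 575 higher and 358 lower. Cholesterol biosynthesis genes fell in 13 of 24 cases and rose in 0. Camera on the cholesterol genes gave adjusted p = 2.39e-15, adjusted p = 0.129 with an estimated correlation, and 0 higher and 17 lower members adjusted over the list alone. Insig1, a regulator of sterol synthesis, changed by -0.36 ± 0.06, adjusted p = 4.30e-04. Its normalised count in females was 2188 ± 283 (SD, n = 5) under vehicle and 1657 ± 137 (SD, n = 5) under fluoxetine, and in males 2134 ± 223 (SD, n = 5) and 1711 ± 129 (SD, n = 5). Sqle, squalene epoxidase, changed by -0.35 ± 0.06, adjusted p = 5.75e-04. Hmgcs1 and Nsdhl changed by -0.38 ± 0.07, adjusted p = 0.00183 and -0.29 ± 0.06, adjusted p = 0.00288. Markers of myelinating oligodendrocytes fell in 10 of 22. Camera gave adjusted p = 2.99e-12 (at most 2.69e-07 over other settings, olfactory ones too) and adjusted p = 0.456 with an estimated correlation. Adjusted over the list alone, 0 members were higher and 14 lower. Tspan2 changed by -0.72 ± 0.14, adjusted p = 0.00145, Ugt8a by -0.69 ± 0.17, adjusted p = 0.0134, Mog by -0.76 ± 0.20, adjusted p = 0.017 and Opalin by -0.79 ± 0.21, adjusted p = 0.0186. Tspan2 was 1995 ± 471 (SD, n = 5) in WT fluoxetine females, the most olfactory group.

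Egr3 and Nptx2, which neuronal activity induces, rose by 0.67 ± 0.11, adjusted p = 3.32e-04 and 0.57 ± 0.10, adjusted p = 4.04e-04 under fluoxetine in WT. Egr3 was 5441 ± 1253 (SD, n = 5) in WT fluoxetine males and 3065 ± 341 (SD, n = 5) in WT vehicle males. In all, 2 of 24 immediate early genes rose and 0 fell. Camera on the immediate early genes, with a median of 0.42 in females and -0.15 in males, gave adjusted p = 0.0345 (0.00486 to 0.874 over other settings, highest without the 14 most olfactory libraries), adjusted p = 0.766 with an estimated correlation, and 2 higher and 0 lower members adjusted over the list alone. Endoplasmic reticulum stress genes rose in 5 of 18, with Hyou1 at 0.26 ± 0.06, adjusted p = 0.00346 and Hspa5 at 0.34 ± 0.08, adjusted p = 0.00856. Camera on the endoplasmic reticulum stress genes gave adjusted p = 2.44e-06, adjusted p = 0.456 with an estimated correlation, and 8 higher and 0 lower members adjusted over the list alone. Postsynaptic density scaffolds rose in 7 of 30, with Sipa1l1 at 0.17 ± 0.04, adjusted p = 0.0121. Camera on the postsynaptic density scaffolds gave adjusted p = 1.16e-04 (4.35e-14 to 0.269 over other settings, highest with GC and length correction), adjusted p = 0.609 with an estimated correlation, and 10 higher and 0 lower members adjusted over the list alone. Autism risk genes rose in 10 of 53, such as Ash1l (0.25 ± 0.05, adjusted p = 0.00351) and Kmt2a (0.28 ± 0.06, adjusted p = 0.00418). Camera on the autism risk genes gave adjusted p = 1.91e-07 (2.80e-09 to 0.221 over other settings, highest with GC and length correction), adjusted p = 0.129 with an estimated correlation, and 14 higher and 0 lower members adjusted over the list alone.

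Of the serotonin system, Maoa, which degrades serotonin, and the receptor gene Htr2c changed by -0.20 ± 0.05, adjusted p = 0.0202 and -0.61 ± 0.19, adjusted p = 0.0488 under fluoxetine in WT. Slc6a4, the serotonin transporter that fluoxetine inhibits, is not listed in the table. Slc5a3 rose by 0.38 ± 0.09, adjusted p = 0.00527. Tpm3-rs7 (-1.33 ± 0.25, adjusted p = 0.00124) and E2f2 (-0.87 ± 0.17, adjusted p = 0.00208) fell. Shank3 had 0.01 ± 0.08, adjusted p = 0.98. Under fluoxetine in WT camera also called microglia markers (-0.15), red blood cell genes (-0.51), glucocorticoid-responsive genes (0.22), oxidative phosphorylation genes (-0.07), ribosomal protein genes (-0.05, females 0.04, males -0.10) and interferon-response genes (0.12) (medians), at adjusted p from 6.22e-05 to 0.0176, and adjusted p of at least 0.458 with an estimated correlation. Microglia markers, oxidative phosphorylation genes, ribosomal protein genes and interferon-response genes lost the call under other settings, and the direction of oxidative phosphorylation genes and ribosomal protein genes turned. The count with fluoxetine was 421 with compared groups only, 2877 with array weights, 1984 with the olfactory covariate, 446 with GC and length correction and 1734 without the 14 most olfactory libraries. It was 462 without WT fluoxetine female replicate 2, and 570 without WT vehicle female replicate 3. For fluoxetine in WT, calls ended without the trend, with the replicate block, with the striatal covariate and with edgeR for Htr2c, with compared groups only for Sipa1l1, Maoa and Htr2c, with GC and length correction for Sipa1l1, Ugt8a, Htr2c, Nsdhl and Kmt2a, without the 14 most olfactory libraries for Opalin, Sipa1l1, Ugt8a, Htr2c and Kmt2a. Maoa (1) and Htr2c (13) lost calls without any 1 of that many libraries.

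In HT mice fluoxetine against vehicle gave 0 called genes with limma and 0 with edgeR when the sexes were averaged, while 1307 genes had an unadjusted p under 0.05, against 901.3 by chance. The smallest adjusted p was 0.109. Values on the higher side were Pml (0.24 ± 0.05), Ncan (0.27 ± 0.06) and Sphk2 (0.25 ± 0.06), and on the lower side Mrps18c (-0.34 ± 0.07), Usmg5 (-0.24 ± 0.05) and Selenof (-0.19 ± 0.04). Cholesterol biosynthesis genes had a median of -0.15, with 0 called over all genes. Camera on the cholesterol genes gave adjusted p = 7.80e-11, adjusted p = 0.428 with an estimated correlation, and 0 higher and 11 lower members adjusted over the list alone. Nsdhl and Stard4 had -0.28 ± 0.07, adjusted p = 0.135 and -0.29 ± 0.08, adjusted p = 0.232. Endoplasmic reticulum stress genes had a median of 0.10, with 0 called. Camera on the endoplasmic reticulum stress genes gave adjusted p = 8.63e-05, adjusted p = 0.428 with an estimated correlation, and 0 members adjusted over the list alone. Red blood cell genes had a median of -0.51, with 0 of 5 called. Camera on the red blood cell genes, with a median of -1.07 in females and 0.04 in males, gave adjusted p = 8.63e-05, adjusted p = 0.428 with an estimated correlation, and 0 members adjusted over the list alone. Shank3 had 0.04 ± 0.09, adjusted p = 0.994. Under fluoxetine in HT camera also called postsynaptic density scaffolds (0.07, females 0.16, males -0.02), astrocyte markers (0.06), choroid plexus markers (-0.52), lysosomal genes (0.03, females 0.09, males -0.01), heat shock chaperones (0.08, females 0.18, males -0.01), oxidative phosphorylation genes (-0.04, females -0.11, males 0.03) and autism risk genes (0.05, females 0.11, males -0.02) (medians), at adjusted p from 8.63e-05 to 0.0477, and adjusted p of at least 0.428 with an estimated correlation. Postsynaptic density scaffolds, choroid plexus markers, lysosomal genes, oxidative phosphorylation genes and autism risk genes lost the call under other settings. The count in HT was 163 with array weights and 18 with the olfactory covariate. It was 1 and 3 without HT vehicle female replicates 2 and 5, and 1 and 1 without HT vehicle male replicates 2 and 3. The fluoxetine by genotype interaction called 0 genes with limma and 0 with edgeR, with 634 at an unadjusted p under 0.05, so the fluoxetine effects in HT and WT were not shown to differ.

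Across genes, the fluoxetine effects in HT and WT, which share no library, had r = 0.30 (simulated range -0.45 to 0.47, permutation p = 0.109, adjusted p = 0.327, covariance 0.0121, simulated -0.000705). In WT, 440 genes were called higher under both drugs and 199 lower, with 0 in opposite directions. Independent lists would give 40.5 and 16.6, but both comparisons use the WT vehicle libraries. Their r was 0.60 against a simulated mean of 0.48 with no effect (permutation p = 0.198, adjusted p = 0.396, covariance 0.0301, simulated 0.0176). In HT the corresponding r was 0.60 against 0.52 (permutation p = 0.287, adjusted p = 0.431, covariance 0.0268, simulated 0.0204). They averaged 0.23 (0.11 to 0.31) in WT and 0.11 (0.04 to 0.17) in HT over 20 splits with separate vehicle libraries.

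Whether a drug moved genes in HT mice against the genotype effect was asked with the correlation of both effects. They share the HT vehicle libraries with opposite sign. For fluoxetine r was -0.48 against a simulated mean of -0.55 (permutation p = 0.812, adjusted p = 0.901, covariance -0.0189, simulated -0.0211). For lithium r was -0.37 against -0.53 (permutation p = 0.901, adjusted p = 0.901, covariance -0.0179, simulated -0.0205). Both r were weaker than their simulated mean, a side this p does not test. They averaged -0.01 (-0.10 to 0.18) and 0.01 (-0.10 to 0.19) over 20 splits with separate vehicle libraries. Across sexes, where no library is shared, r was -0.02 and 0.04 for fluoxetine and 0.14 and -0.10 for lithium. The permutation p values were 0.901, 0.743, 0.337 and 0.465, and 0.901, 0.901, 0.838 and 0.838 adjusted over 9 correlations across sexes.

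HT and WT mice that both received lithium differed in 0 genes by limma and 0 by edgeR, with 1771 at an unadjusted p under 0.05. The smallest p values belonged to Zfp524 (0.43 ± 0.09), Nkd1 (0.37 ± 0.08) and Bin2 (0.43 ± 0.10) on the higher side and Arrdc3 (-0.34 ± 0.08), Mctp1 (-0.48 ± 0.11) and Sesn3 (-0.17 ± 0.04) on the lower side. Shank3 had 0.34 ± 0.09, adjusted p = 0.214. Myelin markers had a median of -0.50, with 0 called, and Mal had -0.70 ± 0.22, adjusted p = 0.294. Camera on the myelin markers gave adjusted p = 5.73e-12 (7.40e-20 to 0.469 over other settings, highest without the 14 most olfactory libraries), adjusted p = 0.66 with an estimated correlation, and 0 higher and 15 lower members adjusted over the list alone. Between these groups camera also called postsynaptic density scaffolds (0.06), upper-layer excitatory markers (0.12), deep-layer excitatory markers (-0.12), microglia markers (0.17), endothelial and pericyte markers (0.09), olfactory and thalamic markers (-0.27), glucocorticoid-responsive genes (-0.09), endoplasmic reticulum stress genes (0.06), oxidative phosphorylation genes (0.04) and ribosomal protein genes (0.04) (medians), at adjusted p from 5.84e-07 to 0.044, and adjusted p of at least 0.66 with an estimated correlation. Upper-layer excitatory markers, deep-layer excitatory markers, endothelial and pericyte markers, olfactory and thalamic markers, glucocorticoid-responsive genes, endoplasmic reticulum stress genes, oxidative phosphorylation genes and ribosomal protein genes lost the call under other settings. The count under lithium was 81 with array weights, 10 with the olfactory covariate, 7 with GC, length and olfactory correction and 828 without the 14 most olfactory libraries. It was 1 without HT lithium female replicate 3, 1 without WT lithium female replicate 1, and 1 without WT lithium male replicate 5.

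Under fluoxetine HT and WT mice differed in 0 genes by limma and 1 by edgeR, with 2023 at an unadjusted p under 0.05. Immediate early genes had a median of -0.32, with 0 called, and Egr3 and Fosb had -0.54 ± 0.11, adjusted p = 0.14 and -0.73 ± 0.24, adjusted p = 0.277. Camera on the immediate early genes gave adjusted p = 1.65e-10, adjusted p = 0.537 with an estimated correlation, and 0 higher and 8 lower members adjusted over the list alone. Shank3 had 0.08 ± 0.08, adjusted p = 0.734. For these mice camera also called GABA receptors (0.09), myelin markers (0.19), microglia markers (0.09), meningeal fibroblast markers (-0.18), cholesterol genes (0.07), mitochondrially encoded genes (0.13), ribosomal protein genes (-0.05) and interferon-response genes (-0.12) (medians), at adjusted p from 2.66e-04 to 0.0492, and adjusted p of at least 0.998 with an estimated correlation. All of these lost the call under other settings, and the direction of GABA receptors, meningeal fibroblast markers, cholesterol genes and ribosomal protein genes turned. The count under fluoxetine was 1071 with array weights, 1 with edgeR, 2 with GC, length and olfactory correction and 1 without the 14 most olfactory libraries. It was 2 and 143 without WT fluoxetine female replicates 1 and 5, and 1 without WT fluoxetine male replicate 5.

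**Figure D4:**
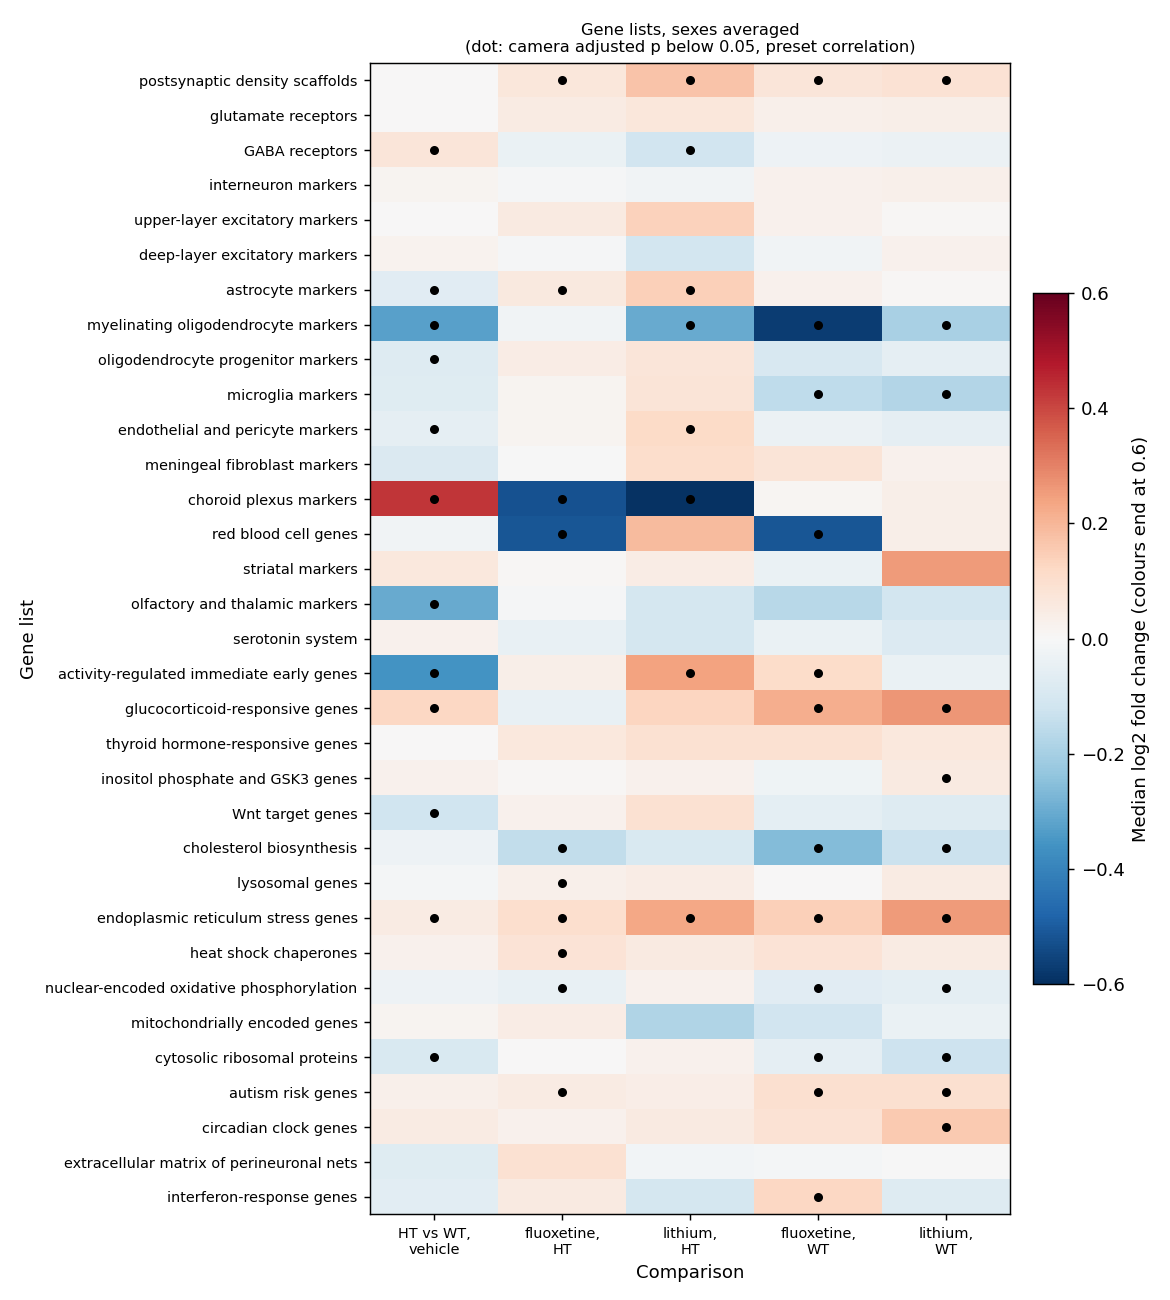
Colours give the median log2 fold change of each gene list (vertical axis) in 5 comparisons with the sexes averaged (horizontal axis). Dots mark a camera adjusted p below 0.05 with the preset correlation, and with an estimated correlation no list was called. Endoplasmic reticulum stress genes had medians of 0.23 and 0.26 under lithium in HT and WT.

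Within HT females lithium gave 1003 genes higher and 891 lower, with Lars2 at 1.21 ± 0.24, adjusted p = 5.72e-04 and Map3k6 at 0.94 ± 0.20, adjusted p = 0.00143. In HT males it gave 1 gene higher and 2 lower. The difference between the sexes, males minus females, called 31 genes. They included Usmg5, a subunit of ATP synthase (0.75 ± 0.11, adjusted p = 2.36e-04), and Tomm5, of the import pore of the outer mitochondrial membrane (0.75 ± 0.12, adjusted p = 4.01e-04). Chchd1 and Rpl17, ribosomal proteins of the mitochondrion and the cytosol, had 0.95 ± 0.15, adjusted p = 4.54e-04 and 0.67 ± 0.11, adjusted p = 4.85e-04. The count in HT females was 248 with compared groups only, 4155 with array weights, 3043 with the olfactory covariate and 620 with GC and length correction. It was 1245 without HT vehicle female replicate 3. The count in HT males was 1 without the trend, 1 with TMM factors, 55 with compared groups only, 1 with the replicate block, 1 with the striatal covariate, 692 with array weights, 38 with the olfactory covariate, 0 with GC and length correction, 1 with GC, length and olfactory correction and 95 without the 14 most olfactory libraries. It was 1, 0, 0 and 0 without HT lithium male replicates 1, 2, 3 and 4, and 0, 1 and 0 without HT vehicle male replicates 1, 2 and 3. The count for the difference was 5 with compared groups only, 858 with array weights, 58 with the olfactory covariate, 8 with GC and length correction, 14 with GC, length and olfactory correction and 52 without the 14 most olfactory libraries. It was 54 and 17 without HT lithium female replicates 1 and 3, 14, 10, 18 and 17 without HT lithium male replicates 1, 2, 3 and 4, 17, 13, 12 and 73 without HT vehicle female replicates 2, 3, 4 and 5, and 66, 9 and 5 without HT vehicle male replicates 1, 2 and 3. For the difference, calls ended with GC and length correction for Tomm5 and Chchd1.

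Within WT, lithium gave 694 genes higher and 500 lower in females and 272 genes higher and 143 lower in males. Between the sexes 0 genes differed by limma and 0 by edgeR, with 1556 at an unadjusted p under 0.05. In males Tekt4 rose (1.98 ± 0.39, adjusted p = 0.00247) and Aplnr fell (-1.72 ± 0.36, adjusted p = 0.00486). The count in WT females was 609 with compared groups only, 2041 with array weights, 2259 with the olfactory covariate and 350 with GC and length correction. It was 795 and 485 without WT lithium female replicates 2 and 4. The count in WT males was 155 with compared groups only, 1088 with array weights, 1130 with the olfactory covariate, 1122 with GC, length and olfactory correction and 884 without the 14 most olfactory libraries. It was 143 without WT lithium male replicate 4, and 177, 184 and 230 without WT vehicle male replicates 3, 4 and 5. In WT males calls ended with compared groups only for Tekt4 and Aplnr. Aplnr (1) lost the call without any 1 of that many libraries. The count for the difference was 1 with compared groups only, 29 with array weights, 12 with the olfactory covariate, 1 with GC and length correction, 4 with GC, length and olfactory correction and 6 without the 14 most olfactory libraries. It was 1 without WT lithium female replicate 2, 1 without WT lithium male replicate 2, and 4 without WT vehicle female replicate 4.

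Fluoxetine in HT females gave 71 genes higher and 60 lower. Lars2 (1.12 ± 0.24, adjusted p = 0.012) and Gaa (0.53 ± 0.10, adjusted p = 0.0064) rose. Usmg5 (-0.58 ± 0.07, adjusted p = 1.76e-06) and Chchd1 (-0.57 ± 0.10, adjusted p = 0.0019) fell. In HT males 0 genes were called by limma and 0 by edgeR, with 644 at an unadjusted p under 0.05. Between the sexes 5 genes differed: Usmg5 (0.67 ± 0.11, adjusted p = 0.00193), Rpl17 (0.61 ± 0.10, adjusted p = 0.0029), Chchd1 (0.85 ± 0.15, adjusted p = 0.0029), Tomm5 (0.59 ± 0.11, adjusted p = 0.0182) and Med21 (0.62 ± 0.13, adjusted p = 0.0393). The count in HT females was 0 with compared groups only, 749 with array weights, 421 with the olfactory covariate, 28 with GC and length correction and 72 without the 2 libraries apart. It was 63 and 9 without HT fluoxetine female replicates 1 and 5, and 45, 61, 9 and 304 without HT vehicle female replicates 1, 2, 3 and 5. In HT females calls ended with compared groups only for Lars2, Gaa, Usmg5 and Chchd1. Lars2 (3) and Gaa (2) lost calls without any 1 of that many libraries. The count in HT males was 5 with array weights. It was 1 without HT vehicle male replicate 2. The count for the difference was 0 with compared groups only, 75 with array weights, 8 with the olfactory covariate, 2 with GC and length correction, 3 with GC, length and olfactory correction and 15 without the 14 most olfactory libraries. It was 3 without HT fluoxetine female replicate 4, 3 without HT fluoxetine male replicate 4, 3 without HT vehicle female replicate 3, and 1 without HT vehicle male replicate 3. Calls of the difference ended with compared groups only for Usmg5, Rpl17, Chchd1, Tomm5 and Med21, with GC and length correction for Chchd1, Tomm5 and Med21. Med21 (11), Tomm5 (6), Rpl17 (1) and Chchd1 (1) lost calls without any 1 of that many libraries.

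Fluoxetine in WT females gave 1021 genes higher and 1168 lower, including the neuronal RNA gene Bc1 (-1.78 ± 0.37, adjusted p = 0.00115). As many or more genes were called in 6 of 100 splits of these libraries, the real one included. Bc1 had -0.77, adjusted p = 0.39 without the 14 most olfactory libraries. In WT males it gave 114 genes higher and 71 lower, including Zfp189 (1.18 ± 0.19, adjusted p = 4.51e-04). The difference between the sexes called 1395 genes, with Btbd17 at -1.34 ± 0.22, adjusted p = 0.00185. The effects in WT females and males correlated with the GC content of the transcript in opposite directions, with Spearman's rho across genes of 0.48 and -0.34. The count in WT females was 12 with compared groups only, 4959 with array weights, 432 with GC and length correction, 490 with GC, length and olfactory correction and 834 without the 14 most olfactory libraries. It was 972, 1303 and 3479 without WT fluoxetine female replicates 2, 4 and 5, and 1375 without WT vehicle female replicate 3. In WT females calls ended with compared groups only and without the 14 most olfactory libraries for Bc1. The count in WT males was 54 with compared groups only, 114 with the striatal covariate, 1242 with array weights, 698 with the olfactory covariate, 74 with GC and length correction, 333 with GC, length and olfactory correction, 340 without the 2 libraries apart and 329 without the 14 most olfactory libraries. It was 50, 29 and 435 without WT fluoxetine male replicates 1, 3 and 5, and 321, 41, 40 and 40 without WT vehicle male replicates 2, 3, 4 and 5. The count for the difference was 378 with compared groups only, 4624 with array weights, 2 with GC and length correction, 9 with GC, length and olfactory correction and 0 without the 14 most olfactory libraries. It was 858, 503, 2196, 790 and 2809 without WT fluoxetine female replicates 1, 2, 3, 4 and 5, 481 and 893 without WT fluoxetine male replicates 1 and 3, 883 without WT vehicle female replicate 1, and 864 and 531 without WT vehicle male replicates 3 and 4. The call ended without the 14 most olfactory libraries for Btbd17, which had -1.42, adjusted p = 0.0835 there.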

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

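In this part the counts of other splits, and the tests of a GC and length trend and of olfactory tissue behind the sex difference under fluoxetine, were written down after the results were known; the tests on lithium and on cholesterol genes were written before, but with settings (GC and length, olfactory level, myelin score) chosen after the data were seen. Of 55 tests of a group for a library far from the rest, over 5 measures, 5 found one, where chance gives 2.75. HT fluoxetine female replicate 5 had 35916099 reads, the others of its group 26182208 to 28331063. HT lithium female replicate 4 had 22984556, the others 29791345 to 30744112. HT fluoxetine male replicate 5 had an olfactory level of 2.61, the others 0.094 to 0.438. HT vehicle female replicate 1 lay 5.30 log2 units above the median of libraries in choroid plexus markers, the others between -0.41 and 0.35. WT vehicle male replicate 4 lay at -0.22 in mitochondrially encoded genes, the others between 0.079 and 0.14.

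Differences between groups passed the test of the difference itself in 4 comparisons. The fluoxetine effect in HT differed between the sexes in 5 genes (males minus females, log2: Usmg5 0.67, Rpl17 0.61, Chchd1 0.85, Tomm5 0.59, Med21 0.62). The lithium effect in HT did so in 31 genes, among them Usmg5 0.75, Tomm5 0.75, Chchd1 0.95, Rpl17 0.67, Timm8b 0.71. The fluoxetine effect in WT did so in 1395 genes, among them Btbd17 -1.34, Nae1 0.68, Actr6 0.63, Pcx -0.60. The lithium effect differed between genotypes in 3 genes, Nkd1 0.61, Vwa1 0.64, Nhsl2 -0.38 (HT minus WT). With GC and length correction the calls ended of Chchd1 (0.63), Tomm5 (0.40) and Med21 (0.53) for fluoxetine in HT, Tomm5 (0.46), Chchd1 (0.60) and Timm8b (0.31) for lithium in HT, Nae1 (0.40), Actr6 (0.30) and Pcx (-0.37) for fluoxetine in WT and Vwa1 (0.55) and Nhsl2 (-0.31) for the interaction. With compared groups only those ended of all 5 genes for fluoxetine in HT, Timm8b for lithium in HT and Nhsl2 for the interaction. Without the 2 libraries apart those of Nkd1 (0.56), Vwa1 (0.67) and Nhsl2 (-0.38) ended. Without the 14 most olfactory libraries those of Btbd17 (-1.42), Nae1 (0.67), Actr6 (0.58) and Pcx (-0.49) did.

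The first pattern is the sex difference of the fluoxetine effect in WT, 1395 genes. The median size of these log2 differences was 0.46 (median SE 0.13). It was 0.39 (0.12) with the olfactory covariate, which argues against olfactory tissue as the whole cause. The covariate's 1551 calls do not, as other counts rose too. Without the 14 most olfactory libraries 0 were called, with 2 of the 5 WT fluoxetine females left, while differences named above kept sign. With GC and length correction 2 were called. The median fell to 0.26 (0.11) and 99.9% kept sign, so differences shrank rather than errors grew. A GC and length trend may thus account for much of this difference, while the rest and an effect of sex stay open.

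The second pattern is the 689 genes that lithium changed the same way in HT and WT, against 103.8 for independent lists. After the GC and length correction 195 genes were called the same way in both, against 15.7, and 0 in opposite directions. With the olfactory covariate it was 1338, against 309.0, and 8 in opposite directions. Both values argue against either as the whole cause of the overlap, although the correction lowered the number. Independent lists ignore that genes move together, and the correlation of both effects had a permutation p of 0.0594 (adjusted p = 0.327; unadjusted 0.0099 to 0.099 over the other settings), so agreement by chance is not settled beside an effect of lithium shared by both genotypes, with shared exposure of litters untested.

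The third pattern is the fall of cholesterol biosynthesis genes under fluoxetine in WT, with a median log2 change of -0.26 and 13 of 24 called. The median was -0.24 with GC and length correction (11 called) and -0.23 with the olfactory covariate (15). It was -0.21 with the myelin score as covariate (10). Each argues against that explanation as the whole cause. Left open are an effect of fluoxetine, found and tested on the same data, shared litters and chance in WT vehicle libraries. The list was not called with an estimated correlation (adjusted p = 0.129).

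Other splits of the same libraries, with labels exchanged within sex (and within genotype for interactions), were fitted for each count. There were 100, the real one included, unless another number is given. Brackets give the real count where above 0, the splits with as many genes (1 of 100 unless given) and the highest other count. Drugs are set against vehicle, with sexes averaged unless one is named. With no adjustment over comparisons, chance can be excluded at 1 in 20 for lithium in HT (1761, 379) and HT females (1894, 938). So it can for lithium in HT males (3, 1 of 35, 0), WT (2109, 95), WT females (1194, 500) and WT males (415, 33). Fluoxetine in WT (933, 2 of 100, 1703) meets this limit too, but another split gave more genes than the real one. Chance can also be excluded for fluoxetine in WT males (185, 38) and HT females (131, 4). So it can for HT versus WT in vehicle males (47, 1 of 56, 20). Exchanging single pups does not exclude litter differences. Without any 1 library the 3 genes of lithium in HT males became 0 to 1 (0 with GC and length correction). The 47 of HT versus WT became 1 to 86. Exchanging drug labels gives no drug effect at all, not an equal one in both sexes or genotypes. So the splits do not test the sex difference of fluoxetine in HT (5, 3 of 100, 8) or lithium in HT (31, 5). Nor do they test that of fluoxetine in WT (1395, 1115) or the lithium by genotype interaction (3, 2).

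Chance cannot be excluded for fluoxetine in WT, females (2189, 6 of 100, 4230). Where the real count was 0 every split is as large, so the splits test nothing. This holds for HT versus WT in vehicle (highest count 14), fluoxetine in HT (1), and HT versus WT under fluoxetine (1601) and lithium (8). It holds for HT versus WT in vehicle females (1) and fluoxetine in HT males (1, 56 splits). It also holds for sex differences of HT versus WT in vehicle (56) and lithium in WT (238), and the fluoxetine by genotype interaction (2262). Counts of 4230, 2262 and 1601 arose in comparisons with the WT fluoxetine libraries, which points to a structure that the groups do not give. The main axis of residual variation (19.6%) had r = -0.97 with the olfactory level, not tested as the cause.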

How the results depend on the processing

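Of these settings, edgeR, the olfactory covariate, the GC and length correction, both together and leaving out several libraries were chosen after seeing the data. With no filter, a pseudocount of 5, TMM factors or no trend, the counts stayed within 1.5 times, except for lithium in HT males. Of 157 gene values, part of the rule's output, 155 kept sign and side of the threshold with TMM factors and 151 with edgeR. So did 137 with array weights, 127 with compared groups only, 145 with the olfactory covariate and 108 with GC and length correction. Of 73 called list tests, 71 did so with TMM factors, 56 with array weights, 58 with the olfactory covariate, 51 with GC and length correction, 50 with GC, length and olfactory correction (6 turned), 46 without the 14 most olfactory libraries (5 turned) and 0 with an estimated correlation. The replicate numbers do not pair the mice: residuals of libraries with the same number had a mean correlation of -0.0026, and other numbers 0.00055. edgeR and the compared groups only gave no list values, and edgeR no correlations. Genes below the filter were not tested at this depth. For the changes below, given as counts of called genes or as values, the cause was not tested.

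Without the trend: lithium in HT, males 1.

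With TMM factors: lithium in HT, males 1.

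With compared groups only: HT versus WT in vehicle 1, fluoxetine in WT 421, HT versus WT in vehicle, males 16, fluoxetine in HT, females 0, lithium in HT, females 248, lithium in HT, males 55, fluoxetine in WT, females 12, fluoxetine in WT, males 54, lithium in WT, females 609, lithium in WT, males 155, HT versus WT in vehicle, sex difference 6, fluoxetine in HT, sex difference 0, lithium in HT, sex difference 5, fluoxetine in WT, sex difference 378, lithium in WT, sex difference 1, correlation of fluoxetine effects in HT and WT 0.30 (permutation p = 0.0396), correlation of lithium effects in HT and WT 0.34 (permutation p = 0.0495).

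With the replicate block: HT versus WT in vehicle, males 21, lithium in HT, males 1.

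With the striatal covariate: lithium in HT, males 1, fluoxetine in WT, males 114, HT versus WT in vehicle, sex difference 3.

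With array weights: HT versus WT in vehicle 2, fluoxetine in HT 163, lithium in HT 3452, fluoxetine in WT 2877, lithium in WT 3349, HT versus WT under fluoxetine 1071, HT versus WT under lithium 81, HT versus WT in vehicle, males 960, fluoxetine in HT, females 749, fluoxetine in HT, males 5, lithium in HT, females 4155, lithium in HT, males 692, fluoxetine in WT, females 4959, fluoxetine in WT, males 1242, lithium in WT, females 2041, lithium in WT, males 1088, HT versus WT in vehicle, sex difference 151, fluoxetine in HT, sex difference 75, lithium in HT, sex difference 858, fluoxetine in WT, sex difference 4624, lithium in WT, sex difference 29, lithium by genotype interaction 33, correlation of fluoxetine effects in HT and WT 0.31 (permutation p = 0.0495).

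With edgeR: HT versus WT under fluoxetine 1, HT versus WT in vehicle, females 1.

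With the olfactory covariate: fluoxetine in HT 18, lithium in HT 3168, fluoxetine in WT 1984, lithium in WT 3486, HT versus WT under lithium 10, HT versus WT in vehicle, males 118, fluoxetine in HT, females 421, lithium in HT, females 3043, lithium in HT, males 38, fluoxetine in WT, males 698, lithium in WT, females 2259, lithium in WT, males 1130, fluoxetine in HT, sex difference 8, lithium in HT, sex difference 58, lithium in WT, sex difference 12, lithium by genotype interaction 10, Shank3, HT versus WT in vehicle -0.022, Shank3, HT versus WT under fluoxetine -0.0433, correlation of fluoxetine effects in HT and WT 0.27 (permutation p = 0.0297), correlation of lithium effects in HT and WT 0.34 (permutation p = 0.0099), cholesterol biosynthesis, HT versus WT under fluoxetine -0.00568.

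With GC and length correction: lithium in HT 394, fluoxetine in WT 446, HT versus WT in vehicle, males 18, fluoxetine in HT, females 28, lithium in HT, females 620, lithium in HT, males 0, fluoxetine in WT, females 432, fluoxetine in WT, males 74, lithium in WT, females 350, HT versus WT in vehicle, sex difference 3, fluoxetine in HT, sex difference 2, lithium in HT, sex difference 8, fluoxetine in WT, sex difference 2, lithium in WT, sex difference 1, lithium by genotype interaction 1, Shank3, fluoxetine in HT -0.0555, Shank3, fluoxetine in WT -0.0867, Shank3, lithium in WT -0.0294, cytosolic ribosomal proteins, fluoxetine in WT 0.0104, nuclear-encoded oxidative phosphorylation, lithium in WT 0.0143, autism risk genes, lithium in WT -0.0059.

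With GC, length and olfactory correction: HT versus WT under fluoxetine 2, HT versus WT under lithium 7, lithium in HT, males 1, fluoxetine in WT, females 490, fluoxetine in WT, males 333, lithium in WT, males 1122, HT versus WT in vehicle, sex difference 5, fluoxetine in HT, sex difference 3, lithium in HT, sex difference 14, fluoxetine in WT, sex difference 9, lithium in WT, sex difference 4, lithium by genotype interaction 5, Shank3, fluoxetine in HT -0.0647, Shank3, fluoxetine in WT -0.0488, Shank3, lithium in WT -0.0373, correlation of fluoxetine effects in HT and WT 0.25 (permutation p = 0.0396), correlation of lithium effects in HT and WT 0.35 (permutation p = 0.0099), nuclear-encoded oxidative phosphorylation, fluoxetine in WT 0.0121, cytosolic ribosomal proteins, fluoxetine in WT 0.00386, nuclear-encoded oxidative phosphorylation, lithium in WT 0.015, autism risk genes, lithium in WT -0.00176, GABA receptors, HT versus WT under fluoxetine -0.00562, cholesterol biosynthesis, HT versus WT under fluoxetine -0.000211.

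Without the 2 libraries apart: fluoxetine in HT, females 72, fluoxetine in WT, males 340, HT versus WT in vehicle, sex difference 4, lithium by genotype interaction 0, Shank3, fluoxetine in HT -0.00916, correlation of lithium effects in HT and WT 0.33 (permutation p = 0.0495).

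Without the 14 most olfactory libraries: HT versus WT in vehicle 4, lithium in HT 3042, fluoxetine in WT 1734, HT versus WT under fluoxetine 1, HT versus WT under lithium 828, HT versus WT in vehicle, males 220, lithium in HT, males 95, fluoxetine in WT, females 834, fluoxetine in WT, males 329, lithium in WT, males 884, HT versus WT in vehicle, sex difference 27, fluoxetine in HT, sex difference 15, lithium in HT, sex difference 52, fluoxetine in WT, sex difference 0, lithium in WT, sex difference 6, lithium by genotype interaction 902, Shank3, HT versus WT under fluoxetine -0.11, correlation of lithium effects in HT and WT 0.24 (permutation p = 0.0297), correlation of fluoxetine and lithium effects in WT 0.55 (permutation p = 0.0396), myelinating oligodendrocyte markers, lithium in HT 0.0783, GABA receptors, HT versus WT under fluoxetine -0.0245, meningeal fibroblast markers, HT versus WT under fluoxetine 0.0251, cholesterol biosynthesis, HT versus WT under fluoxetine 0.00486, cytosolic ribosomal proteins, HT versus WT under fluoxetine 0.0162.

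With an estimated correlation: gene list tests 0.

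Leaving out 1 library at a time gave these ranges: fluoxetine in HT 0 to 3, HT versus WT under fluoxetine 0 to 143, fluoxetine in HT, females 9 to 304, fluoxetine in HT, sex difference 1 to 7, Shank3, fluoxetine in HT -0.00916 to 0.075, fluoxetine in HT, males 0 to 1, lithium in HT 995 to 1958, HT versus WT under lithium 0 to 1, lithium in HT, females 1245 to 2065, lithium in HT, sex difference 5 to 73, lithium by genotype interaction 0 to 5, Gsk3a, lithium in HT -0.0477 to 0.00347, correlation of lithium effects in HT and WT 0.30 to 0.36 (permutation p = 0.0198 to 0.0891, under 0.05 in 18 of 36 fits), lithium in HT, males 0 to 1, HT versus WT in vehicle 0 to 1, HT versus WT in vehicle, sex difference 0 to 18, HT versus WT in vehicle, males 1 to 86, fluoxetine in WT 462 to 1295, fluoxetine in WT, females 972 to 3479, fluoxetine in WT, sex difference 481 to 2809, Shank3, fluoxetine in WT -0.0514 to 0.0647, fluoxetine in WT, males 29 to 435, lithium in WT, females 485 to 1095, lithium in WT, sex difference 0 to 4, lithium in WT, males 143 to 486.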

Other observations

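Across genes, the effects in females and in males, which share no library, had Pearson's r = 0.23 for lithium in WT and 0.11 for lithium in HT. For fluoxetine r was -0.07 in WT and 0.02 in HT, and for genotype 0.10. The permutation p values were 0.119, 0.465, 0.594, 0.871 and 0.426, none under 0.838 when adjusted over 9 correlations across sexes.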
